A study of Rattus norvegicus with 4 samples.

How the data were processed

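The cells were rat hepatic stellate cells. Per the labels, total RNA was isolated with an RNeasy kit, amplified and labelled with an Agilent low-input linear amplification kit, and hybridized to Agilent 4x44K whole rat genome arrays. Per the labels, Cy5 carried the test sample (untreated or endoglin siRNA) and Cy3 the cells given the control siRNA on every array, without a dye swap. The siRNA sequences, the time between transfection and harvest, the days in culture and the way the cells were isolated and checked are not given in the sources used here. All 4 arrays lay on 1 slide and were read in 1 scan, so neither slide nor scan could be taken into the fit.

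The authors extracted the signals with Agilent Feature Extraction 9.5.1.1 per the file headers, and the labels also name Rosetta Resolver. Per the file headers the mean and background signals are scanner intensity values on a linear scale, and the log ratios of Feature Extraction are log10 of Cy5 over Cy3. The deposited value table holds log10 ratios: its values had a correlation of 1 with log10 of Cy5 over Cy3 on the endoglin siRNA arrays and of -1 on both untreated arrays, with differences of at most 0.0048 after turning. The reason for the opposite sign is not given in the sources used here. Direction was taken from the dyes in the labels, and the macrophage markers in Cy3 served as a test of it. Of the 45018 values expected per array, 1 was missing on 1 untreated array. One scanner file lacked a line feed, and lines were therefore split at carriage returns.

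Each array had 45018 spots, of which 43379 were gene spots and 1639 were controls. Mean signals were corrected with the local median background by the normexp method of limma with an offset of 50, and the log2 ratios were normalized within each array by loess with controls at weight 0. Spots flagged as non-uniform or as population outliers were left out (189 and 204 on the untreated arrays, 282 and 289 on the endoglin siRNA arrays), and 0 probes were saturated. The log2 ratios of the remaining spots of a probe were averaged. Of 41012 gene probes, 30021 were well above background in at least 1 channel on at least 2 arrays; 190 of these had an array without a usable spot, which left 29831. The brightest probe stood for each gene name, giving 25520 genes; 3509 names had more than 1 kept probe. Names were brought up to date with a RefSeq gene table of the assembly GRCr8: 6624 genes matched by accession, 3234 by symbol and 2276 by synonym, and 13386 matched nothing and kept the name of the array file.

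Genes were tested with limma 3.58.1 in R 4.3.3 (with version 1.17.8 of data.table) with a model of 2 group means, empirical Bayes variances (prior degrees of freedom 5.28) and Benjamini-Hochberg adjustment at 0.05. The 3 comparisons were endoglin siRNA with control siRNA, untreated with control siRNA, and endoglin siRNA with untreated. The control siRNA RNA was present only as the other dye of each array, so the p-values cover only spread between ratios within groups. All 4 arrays share 1 estimate of that spread. Where arrays shared a control RNA, the p-values leave out the control's own spread; whether they did is not given in the sources used here. Standard errors are those of the moderated fit. Named genes were the 12 highest and the 12 lowest log2 ratios with a symbol among genes that passed, filled where fewer passed with genes of the same sign in both RNA sources, ranked by the smaller of their 2 ratios. To these came endoglin, up to 10 genes per direction that passed against both control siRNA and untreated cells, and in each list the members that passed (at most 4) or else the 2 largest.

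Gene lists were fixed from general knowledge: 16 themes and 5 sets of liver cell markers. The themes were endoglin and its co-receptors, TGF-beta and BMP ligands and Smads, TGF-beta/Smad3 targets, BMP/Smad1/5 targets, myofibroblast and contractile genes, collagens and matrix glycoproteins, matrix proteases and inhibitors, stellate cell quiescence and retinoid genes, interferon response, inflammatory cytokines and chemokines, cholesterol and sterol synthesis, unfolded protein and integrated stress response, p53 targets, cell cycle and DNA replication, immediate-early genes, and angiogenic and vascular signalling. The marker sets were those of sinusoidal endothelial cells, Kupffer cells and macrophages, hepatocytes, cholangiocytes, and portal fibroblasts and mesothelial cells. Lists were tested with camera in limma with a preset correlation between genes of 0.01, adjusted over the 21 lists of a comparison. With an estimated correlation, camera also falls back on the 2 residual degrees of freedom of the fit. Its p-values then rise even for lists whose members are not correlated, so a lost call is no sign of correlation.

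Alternatives were no background correction, the log ratios of Feature Extraction, median centring in place of loess, scaling between arrays after loess, the deposited value table with the untreated columns turned, no filter on dim probes, a filter requiring both channels above background on all arrays, the mean of all probes, an intensity trend in the variances, only the arrays of the group compared, the RNA source as a block, each array left out in turn, and an estimated correlation for the lists. A further alternative, chosen after seeing the data, fitted the background without 10 spots (6 on the pooled untreated and 4 on the pooled endoglin siRNA array) whose local background outshone them by more than 50. With these spots the fitted background SD was 653 in Cy5 and 66.9 in Cy3 on the pooled untreated array, and 296 and 443 on the pooled endoglin siRNA array; without them it was 3.78, 0.96, 0.77 and 1.63. The median absolute deviation of the log2 ratios of gene spots was then 0.179 and 0.175 in place of 0.06 and 0.023. With 1 array left out its group has 1 array, and the spread comes from the other group alone. Lists were also tested with each array left out, and that of the co-receptors without endoglin itself, both likewise chosen after seeing the data. Before loess, the log2 ratio of Cy5 over Cy3 went from 0.05 in the dimmest to 1.53 in the brightest 10% of spots on untreated array 1, from 2.56 to 1.82 on untreated array 2, and from 0.08 to 1.69 and from 0.07 to 1.58 on the endoglin siRNA arrays. Median centring leaves such a dependence in place.

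A result that passed in neither of 2 settings was counted as unchanged even where its sign differed, a rule set after seeing the output; this concerned 51 of 291 list results and 9 of 677 results of named genes. The steps after normalization were tested on simulated log ratios of 25520 genes of which 200 were changed. Genes, arrays and control RNAs were drawn as independent, with the same spread on all arrays. Background correction, loess, differences in spread between arrays and correlation between genes were therefore not covered. In the comparison of endoglin siRNA with control siRNA 94% of 1.5-fold, 98.5% of 2-fold and 100% of 4-fold changes were recovered, with 7 false among 202 calls. In that of untreated with control siRNA the shares were 76.1%, 97% and 100% with 9 false among 191 calls, and in that of endoglin siRNA with untreated 49.3%, 97% and 100% with 13 false among 177 calls. In simulated lists 1 of 1 list shifted by 0.3 was called, and 0 of 20 others.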

Results

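The series examined the function of endoglin, a co-receptor for ligands of the TGF-beta and BMP family, in rat hepatic stellate cells. These are the retinoid-storing pericytes of the liver sinusoid, which become matrix-producing myofibroblasts in fibrosis. Cy5-labelled RNA of untreated cells, or of cells given an siRNA against endoglin, was hybridized together with Cy3-labelled RNA of cells given a control siRNA. There were 4 whole-genome oligonucleotide arrays on 1 slide, 2 for each group. In each group 1 array carried RNA of 1 animal and 1 array carried RNA pooled from 3 animals. The labels do not state whether the single animal was among the pooled ones, nor whether arrays shared a control RNA. On the untreated arrays, 69.3% (1 animal) and 93.3% (pool) of the 43379 gene spots were well above background in Cy5, and 62.3% and 87.2% in Cy3. On the endoglin siRNA arrays these shares were 70.2% and 65.7% in Cy5, and 61.9% and 62.1% in Cy3. A total of 25520 genes were tested, of which 12216 carried a gene symbol. The number of arrays, 2 per group, limits the precision of every value.

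Endoglin mRNA (Eng) fell in cells given the endoglin siRNA. Its log2 ratio to control siRNA cells was -2.40 ± 0.26 (SE, n = 2 arrays), a 5.29-fold lower level with an adjusted p of 0.0050. The ratio was -3.08 on the array of 1 animal and -1.72 on the pooled array. In untreated cells the log2 ratio of Eng to control siRNA cells was -0.39 ± 0.26 (adjusted p = 0.6072). The deposited value table gives the opposite sign for both untreated arrays, and the direction used here follows the dyes named in the labels. Between endoglin siRNA and untreated cells Eng differed by -2.02 ± 0.37 on the log2 scale (-2.73 for 1 animal and -1.31 for the pool), which did not pass the test (adjusted p = 0.177). It passed at -2.09 (adjusted p = 0.033) when the background was fitted without 10 spots that disturbed the fit of both pooled arrays, an alternative chosen after seeing the data. It also passed with the RNA source (1 animal or pool) as a block (adjusted p = 0.0117). The Eng call against control siRNA ended with the log ratios of Feature Extraction or of the deposited value table (both -2.44, adjusted p = 0.0747), with median centring in place of loess (-1.34, adjusted p = 0.2118) and with scaling between arrays (-3.56, adjusted p = 0.4355).

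The comparison of endoglin siRNA with control siRNA asked which transcripts follow the loss of endoglin. The deepest fall was that of A2m, which encodes the protease inhibitor alpha-2-macroglobulin, at -3.12 ± 0.28 on the log2 scale (SE, n = 2 arrays), or 8.71-fold (adjusted p = 0.0041). Secreted matrix-associated proteins followed, with Ccn4 (Wisp1, a matricellular protein) at -2.15 ± 0.24 and Cthrc1 (a secreted protein with a collagen-like repeat) at -1.83 ± 0.20. Genes of the contractile apparatus fell as well: Myh11 (smooth muscle myosin heavy chain) by 1.63, Flnc (the actin cross-linker filamin C) by 1.53 and Cnn1 (calponin) by 1.51. Untreated cells also had negative ratios to control siRNA for Myh11 (-0.99), Flnc (-0.74) and Cnn1 (-0.89). Against untreated cells the differences were -0.65, -0.79 and -0.62, and none of them passed (adjusted p = 0.5559, 0.7294 and 0.6752). The other large falls were those of Tgm2 (a protein cross-linking transglutaminase, -1.54), Hsp90ab1 (a cytosolic chaperone, -1.47), Ptgis (prostacyclin synthase, -1.46) and Them5 (an acyl-CoA thioesterase, -1.40). Their adjusted p-values lay between 8.9e-04 (Hsp90ab1) and 0.0276 (Flnc), and the ratio was negative on both arrays for each of them. The size on 1 array was more than 2 times that on the other (1 animal and pool) for Flnc (-2.34 and -0.72), Cnn1 (-2.06 and -0.97) and Ptgis (-2.06 and -0.86). Cnn1 (-2.43) and Ptgis (-2.22) were more than 1.5 times as large with Feature Extraction log ratios.

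Among the genes that rose, Tmsb4x (the actin-sequestering peptide thymosin beta 4) led with 1.29 ± 0.07, followed by the membrane protein gene Tm4sf1 with 1.23 ± 0.06. Extracellular matrix genes among them were the small leucine-rich proteoglycans Fmod (1.20) and Omd (1.12), the minor fibrillar collagen Col11a1 (1.01) and the elastic fibre protein Fbln5 (0.95). The chemokine gene Cx3cl1 rose by 1.18, B2m (the light chain of MHC class I) by 1.06, and Rapgef5 (an exchange factor for Rap GTPases) by 1.05. Tceal9 (0.99), the aldo-keto reductase gene Akr1c15 (0.96) and the ribosomal protein gene Rps6 (0.94) completed the group. The arrays (1 animal and pool) lay far apart for Rapgef5 (1.52 and 0.58), Col11a1 (1.49 and 0.54), Fbln5 (1.36 and 0.55) and Akr1c15 (1.29 and 0.63). With Feature Extraction log ratios Omd stood at 1.78 and Akr1c15 at 1.72. Untreated cells also had positive ratios to control siRNA for Tmsb4x (0.97), B2m (0.77), Rps6 (0.68) and Tceal9 (0.62), against 0.04 for Tm4sf1 and 0.03 for A2m. Probes of one gene disagreed in places: a second probe gave -0.02 for Myh11, 0.24 for Them5 and 0.14 for Cx3cl1, and the other Col11a1 probes gave -0.01 and 0.95.

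**Figure D1:**
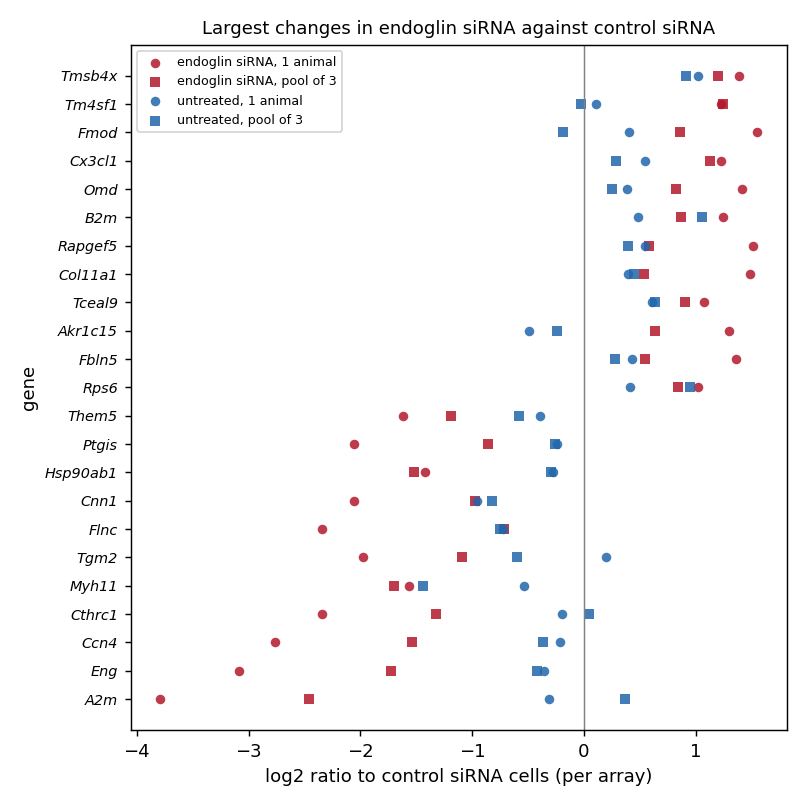
Log2 ratio to control siRNA cells (x axis) of the 12 genes with the highest and the 11 with the lowest mean ratio among those that passed the test in endoglin siRNA cells (y axis), with 1 point per array, coloured by group and shaped by RNA source. Both endoglin siRNA arrays lie on the same side of 0 for every gene, and A2m lies farthest out at -3.79 (1 animal) and -2.46 (pool).

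By limma, 2075 of the 25520 genes differed between endoglin siRNA and control siRNA cells, 1341 higher and 734 lower, and 5888 had an unadjusted p under 0.05. Of the 2075, 49 differed at least 2-fold (13 higher, 36 lower). Regardless of the test, 20 genes were at least 2-fold on both arrays (6 higher, 14 lower), where independent arrays would give 0.1. Without the 10 disturbed spots 4158 genes passed (2286 higher, 1872 lower), among them 1952 of the 2075, and 57 were 2-fold on both arrays. Without background correction 4505 passed and 72 were 2-fold. No gene passed in limma with Feature Extraction log ratios (7110 at an unadjusted p under 0.05), the deposited value table (7106), median centring (6180) or scaling between arrays (1425), and the 2-fold counts were then 302, 300, 2384 and 8. All 2075 genes kept their sign with Feature Extraction log ratios, whereas median centring turned 668 of them. Without the 1-animal endoglin array 898 genes passed, without the pooled one 2683, and without either untreated array 1174; a group left with 1 array takes its spread from the other group alone. The 2-fold counts without these 2 endoglin arrays were 31 and 155. Of the 83 named genes besides Eng that passed, 24 no longer did without the 1-animal endoglin array, 13 without the pooled one and 15 without either untreated array.

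Genes of matrix production were lower on balance. Of 31 measured collagens and matrix glycoproteins, 9 fell and 5 rose (15 and 6 when adjusted over the list alone). Their median log2 ratio of -0.26 passed the list test (adjusted p = 6.3e-04, but adjusted p = 0.5188 with an estimated correlation), and median centring turned the median to 0.70. Col1a1, a chain of the main fibrillar collagen, fell by 0.89, whereas Bgn (the proteoglycan biglycan) rose by 0.91 in addition to Col11a1 and Fbln5; Bgn was also higher in untreated cells (1.19). Among 20 targets of TGF-beta and Smad3, 7 fell and 1 rose (8 and 1 adjusted over the list alone), with a median of -0.21 that median centring turned to 0.67. Their adjusted p was 3.3e-04, and the adjusted p was 0.5188 with an estimated correlation. Examples were Ltbp2 (a matrix protein of the latent TGF-beta binding family, -1.05), Lox (the collagen cross-linking oxidase, -0.67) and Pmepa1 (a feedback inhibitor of TGF-beta signalling, -0.63). Of 19 myofibroblast and contractile genes 6 fell and 3 rose (10 and 6 adjusted over the list alone), with a median of -0.30 (adjusted p = 0.0039, but adjusted p = 0.5188 with an estimated correlation), which median centring turned to 1.03. Here Myh11, Cnn1 and Lox fell, while the growth factor receptor gene Pdgfra rose by 0.62. No probe carried the name Acta2, the gene of smooth muscle actin. The 18 matrix proteases and inhibitors split evenly, with 2 higher and 2 lower (3 and 4 adjusted over the list alone), a median of -0.06 and an adjusted p of 0.3336. Mmp3 (stromelysin, -0.91) and Mmp23 (-0.39) fell, and the inhibitors Timp1 (0.57) and Timp2 (0.35) rose, with 0.32 and 0.11 in Feature Extraction log ratios. Both inhibitors had larger positive ratios to control siRNA in untreated cells. Without the 1-animal endoglin array the medians of collagens and myofibroblast genes were -0.16 and -0.19, and with Feature Extraction log ratios that of TGF-beta targets was -0.33. TGF-beta targets no longer passed with median centring (adjusted p = 0.103). The arrays (1 animal and pool) read -0.96 and -0.38 for Lox and -0.92 and -0.34 for Pmepa1. With median centring Col1a1, Lox, Pmepa1 and Mmp23 had positive ratios (0.45, 0.69, 0.32 and 0.92).

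In the receptor system of endoglin itself, Eng alone passed among 12 co-receptor genes (2 lower adjusted over the list alone). Their median was -0.09 (adjusted p = 0.0039, but adjusted p = 0.6536 with an estimated correlation), and 0.13 with median centring, where the call ended (adjusted p = 0.5558). The median was -0.25 with Feature Extraction log ratios, -0.16 without the disturbed spots, -0.03 without the 1-animal and -0.17 without the pooled endoglin array. This list holds the target of the siRNA; without Eng, an alternative chosen after seeing the data, its median was -0.08 (adjusted p = 0.0227). Of 21 TGF-beta and BMP ligands and Smads, 2 rose and 3 fell (5 and 3 adjusted over the list alone). Bmp4 (0.65; 0.96 for 1 animal and 0.34 for the pool) and the BMP antagonist gene Nog (0.54) rose, and Bmp6 fell (-0.53, but 0.33 with median centring). The median (0.07) and mean (0.02) of this list were positive while its test pointed down (adjusted p = 0.6896). Targets of BMP and Smad1/5 were higher on balance, with 2 of 12 rising (4 adjusted over the list alone), a median of 0.24 and an adjusted p of 0.0158, but an adjusted p of 0.5188 with an estimated correlation. Nog and Id3 (an inhibitor of basic helix-loop-helix factors, 0.39) were the members that passed. Nog stood at 1.06 without the disturbed spots and 1.96 with Feature Extraction log ratios, where Id3 stood at 0.22. This list no longer passed without the pooled endoglin array (median 0.16, adjusted p = 0.0808), without the disturbed spots (0.18, adjusted p = 0.0703) or with Feature Extraction log ratios (0.25, adjusted p = 0.2066), and its median was 0.44 without the 1-animal endoglin array and 0.98 with median centring.

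Lists of cell cycle, sterol synthesis and inflammation also passed. Of 34 cell cycle and DNA replication genes 2 rose (7 adjusted over the list alone), with a median of 0.20 (adjusted p = 3.3e-04, but adjusted p = 0.6308 with an estimated correlation). These were Pcna (the DNA polymerase clamp, 0.48) and Tyms (thymidylate synthase, 0.32). Pcna read 0.28 for 1 animal and 0.67 for the pool, and the list median was 0.87 with median centring. Of 21 genes of cholesterol and sterol synthesis 2 fell (2 adjusted over the list alone), namely Hmgcs1 (-0.54) and Idi1 (-0.43). Their list had a median of -0.13 (adjusted p = 1.7e-05, but adjusted p = 0.6308 with an estimated correlation), which median centring turned to 0.62, with Hmgcs1 at 0.62 and Idi1 at 0.65. The sterol median was -0.29 with Feature Extraction log ratios and -0.23 without the disturbed spots. Of 25 inflammatory cytokines and chemokines 4 rose and 2 fell (7 and 2 adjusted over the list alone), with a median of 0.31 (adjusted p = 0.0159, but adjusted p = 0.792 with an estimated correlation). Besides Cx3cl1, the macrophage growth factor gene Csf1 rose (0.61), while the alarmin gene Il33 (-0.78; -1.10 for 1 animal, -0.46 for the pool and -1.23 with Feature Extraction log ratios) and the chemokine gene Cxcl12 (-0.76, but 0.62 with median centring) fell. The inflammatory list lost its call without the 1-animal endoglin array (median 0.02, adjusted p = 0.518), without the disturbed spots (0.25, adjusted p = 0.0603), with Feature Extraction log ratios (0.29, adjusted p = 0.1161) and with median centring (0.94, adjusted p = 0.0954); without the filter on dim probes its median was 0.19.

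The remaining themes did not pass as lists, though single members did. Among 23 immediate-early genes 6 rose and 2 fell (7 and 2 adjusted over the list alone; median 0.05, adjusted p = 0.2782), with Klf6 at 0.63, Egr1 at 0.56, Dusp6 at 0.56 and Junb at -0.54. Among 18 genes of stellate cell quiescence and retinoid handling 4 rose and 1 fell (6 and 1 adjusted over the list alone; median 0.17, adjusted p = 0.1039). Those that rose included Cygb (cytoglobin, 0.76) and the transcription factor gene Tcf21 (0.45). The member that fell was Nes (nestin, -0.43), and its fall is not read here as a loss of quiescence. The quiescence list passed without either untreated array (adjusted p = 0.0406) or without the 1-animal endoglin array (adjusted p = 7.9e-04). Of 20 genes of the unfolded protein and integrated stress response 3 rose and 2 fell (5 and 5 adjusted over the list alone; median 0.11, adjusted p = 0.8702), with Ddit3 (0.66) and Herpud1 (0.54) opposite to Ddit4 (-0.97) and Calr (-0.71). Of 17 p53 targets 2 rose and 1 fell (4 and 1 adjusted over the list alone; median 0.14, adjusted p = 0.1353), namely Fas (0.48), Bbc3 (0.32) and Phlda3 (-0.60). Of 32 interferon response genes 2 rose and 1 fell (3 and 2 adjusted over the list alone), among them Tlr3 (0.41) and Stat2 (-0.37). The interferon list had a median of 0.01 and a mean of 0.02 with a test pointing down (adjusted p = 0.8702). Of 20 angiogenic and vascular signalling genes 3 rose and 2 fell (3 and 6 adjusted over the list alone), with the vasodilator gene Adm at 0.84, Angpt2 at 0.62, Vegfa at -0.55 and Sphk1 at -0.51. Its median of 0.03 and mean of 0.01 also stood against a test pointing down (adjusted p = 0.586). The arrays (1 animal and pool) read -1.53 and -0.40 for Ddit4, 0.92 and 0.33 for Angpt2, -0.76 and -0.27 for Sphk1, and 0.29 and 0.61 for Tcf21. Without the disturbed spots Sphk1 (-0.86) and Stat2 (-0.58) were more than 1.5 times as large, and with Feature Extraction log ratios so were Sphk1 (-1.02), Stat2 (-0.63), Angpt2 (1.5) and Egr1 (0.89). With median centring the ratios of Junb (0.43), Nes (0.66), Calr (0.48), Phlda3 (0.48), Stat2 (0.32) and Vegfa (0.27) were positive. In the main setting untreated cells also had ratios of the same sign to control siRNA for Cygb, Junb, Phlda3, Calr and Adm. Those of Cygb, Junb and Phlda3 were of similar or larger size than in endoglin siRNA cells.

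Markers of other liver cells did not pass as lists in this comparison in the main setting. The portal list passed without the disturbed spots (median -0.10, adjusted p = 0.0271) and without the filter on dim probes (-0.07, adjusted p = 0.0488). Its median was -0.03 without the 1-animal and -0.16 without the pooled endoglin array. With median centring the endothelial (-0.18, adjusted p = 0.0324), hepatocyte (-0.12, 0.0485) and cholangiocyte lists (-0.03, 0.0485) passed. Of 20 Kupffer cell and macrophage markers only Cd14 rose (0.55, 1 adjusted over the list alone), with a list median of 0.13 and an adjusted p of 0.3292. This median was 0.25 without the pooled and -0.01 without the 1-animal endoglin array. Untreated cells had a similar Cd14 ratio to control siRNA (0.5), with a difference of 0.05 between endoglin siRNA and untreated cells. Of 16 sinusoidal endothelial markers Oit3 (0.88) and the VEGF receptor gene Kdr (0.87) rose and Flt1 (-0.77) fell (2 and 1 adjusted over the list alone). Of 16 hepatocyte markers Cyp2e1 rose (0.48; 1 adjusted over the list alone). The arrays (1 animal and pool) read 0.35 and 0.75 for Cd14, 1.33 and 0.41 for Kdr, -1.07 and -0.47 for Flt1, -1.65 and -0.53 for Sox9, -0.31 and -0.66 for Spp1, and -1.19 and -0.46 for Mfap4. Without the disturbed spots Kdr stood at 1.31 and Cyp2e1 at 0.76, and with Feature Extraction log ratios Kdr at 1.57, Cyp2e1 at 0.94, Flt1 at -1.16 and Mfap4 at -1.54. Both the endothelial list (median 0, mean 0.05) and the hepatocyte list (median 0.02, mean 0.05) had a test pointing down (adjusted p = 0.9193 for each). Of 11 cholangiocyte markers Sox9 (-1.09) and Spp1 (-0.49, but 0.52 with median centring) fell (3 adjusted over the list alone), with a median of 9.8e-04, a mean of -0.18 and a test pointing down (adjusted p = 0.1348). Of 18 portal fibroblast and mesothelial markers Ogn rose (0.76) and Mfap4 (-0.83), Mfap5 (-0.73, but 0.03 with median centring) and Cnn1 fell (1 and 3 adjusted over the list alone; median -0.09, adjusted p = 0.0551). In all, 8 of the 21 lists passed with the preset correlation, 3 upward and 5 downward, and none with an estimated one, where the lowest adjusted p was 0.5188. The estimated test rests on 2 residual degrees of freedom, so this loss need not come from correlated members. Collagens, myofibroblast genes and BMP targets had estimated correlations of -0.014, -0.041 and -0.034, below the preset 0.01. With median centring the median of all genes was 0.317 in this comparison and 0.258 in that of endoglin siRNA with untreated cells, against 0.023 in each with loess, so the turned medians are to be read relative to these values.

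**Figure D2:**
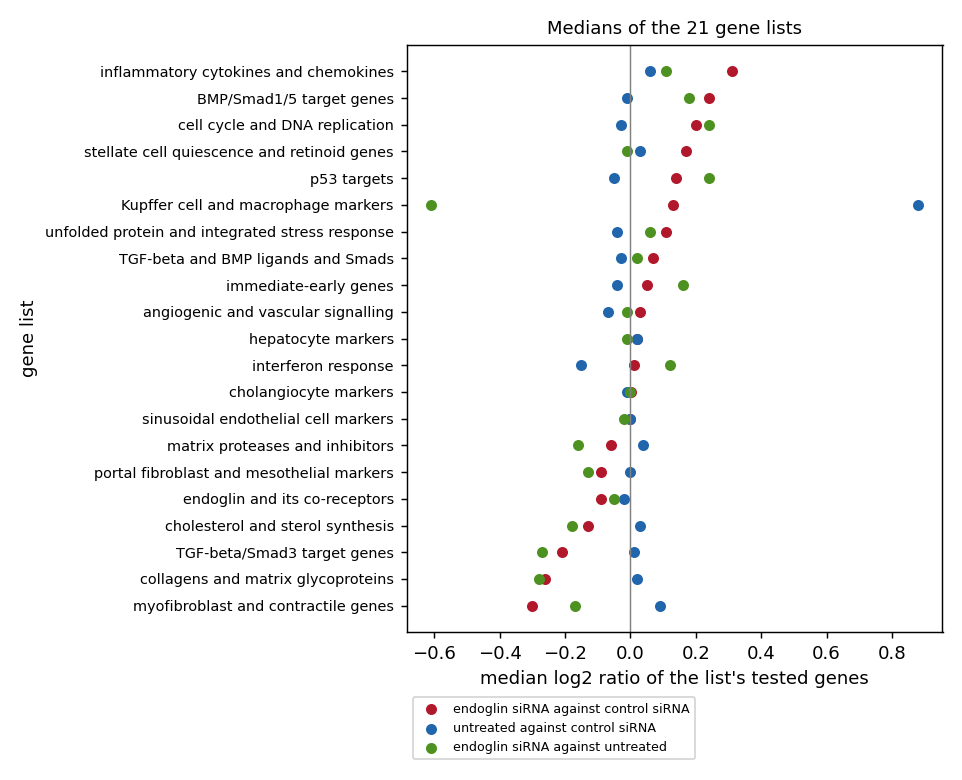
Median log2 ratio (x axis) of the tested genes of each of the 21 gene lists (y axis), with 1 point for each of the 3 comparisons. The macrophage markers stand apart with 0.88 in untreated against control siRNA cells and -0.61 in endoglin siRNA against untreated cells; the medians of collagens, TGF-beta targets and myofibroblast genes lie below 0 for endoglin siRNA and turn positive with median centring.

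The comparison of untreated with control siRNA cells holds any effect of transfection with a control siRNA. Without a dye swap it also holds any dye effect, as well as any other feature of the control RNA. Untreated cells had more mRNA of macrophage genes. Fcrl2, annotated on the array as the macrophage scavenger receptor gene Msr2, was higher by 1.77 ± 0.11 on the log2 scale (SE, n = 2 arrays), or 3.40-fold (adjusted p = 0.0059). Lyz2 (lysozyme) was higher by 1.70 ± 0.25 (1.04 for 1 animal and 2.36 for the pool) and Aif1 (a calcium-binding protein of macrophages) by 1.40 ± 0.14. The myeloid receptor gene Trem2 (1.35) and its signalling adaptor gene Tyrobp (1.34, with a second probe at 0.19) rose together with Coro1a (an actin-binding protein of leukocytes, 1.24), Laptm5 (1.21; 0.75 for 1 animal and 1.66 for the pool), the Fc receptor gene Fcgr1a (1.20) and the lysosomal protease gene Ctss (1.18). Single genes outside this group were higher too: Timp1 (1.20), Bgn (1.19) and Spp1 (osteopontin, 1.18). In the list test collagens and matrix glycoproteins (median 0.02, adjusted p = 0.4147) did not pass. Matrix proteases and inhibitors (0.04, adjusted p = 0.0594) did not pass either.

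Of 20 measured Kupffer cell and macrophage markers, 9 were higher in untreated cells and none lower (18 and 0 adjusted over the list alone). All 20 had positive ratios on both arrays, with a median of 0.88 (adjusted p = 5.1e-24, but adjusted p = 0.4988 with an estimated correlation). The median was 0.95 on the array of 1 animal and 0.63 on the pooled array. In endoglin siRNA cells the same markers had a median of 0.13 against control siRNA (0.25 for 1 animal and -0.01 for the pool).

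**Figure D3:**
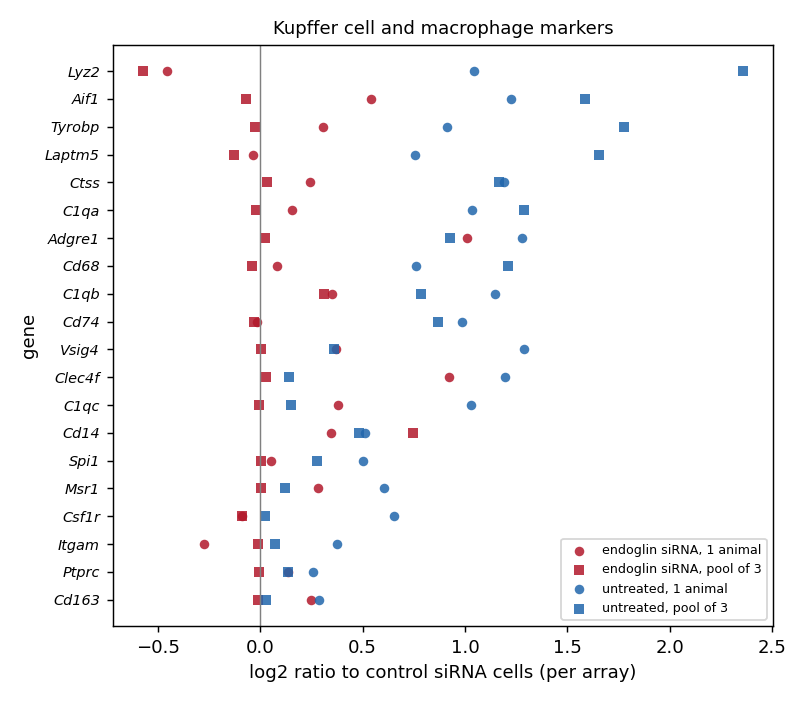
Log2 ratio to control siRNA cells (x axis) of the 20 measured Kupffer cell and macrophage markers (y axis), with 1 point per array, coloured by group and shaped by RNA source. The untreated points lie above 0 for every marker, whereas the endoglin siRNA points scatter around 0 for most of them.

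The genes lower in untreated cells were led by Bst2 (the antiviral membrane protein tetherin) with -1.01 ± 0.12 (adjusted p = 0.0266). Smaller falls concerned Rnf125 (a ubiquitin ligase, -0.76, with a second probe at 0.10), the tetraspanin gene Cd151 (-0.70), Ptprn (-0.64), Rcn3 (-0.64) and the p53 target gene Phlda3 (-0.63). Anp32a (-0.62), Cnpy4 (-0.61), Gnl1 (-0.61), the heparan sulfate proteoglycan gene Sdc1 (-0.59), Tnfrsf12a (-0.56) and the vesicle fusion gene Stx6 (-0.56) were lower by similar amounts. Of all 70 genes that were lower, 66 also passed as lower in endoglin siRNA against control siRNA cells. The ratios there were -0.87 for Sdc1, -0.87 for Rnf125, -0.84 for Cnpy4 and -0.60 for Phlda3. A dye effect or a feature of the control RNA, shared by both comparisons, could also give such falls.

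In the fixed lists, members that were higher in untreated cells included Col3a1 (1.06) next to Bgn among collagens and matrix glycoproteins (2 higher of 31; 5 higher and 2 lower adjusted over the list alone). Among proteases and inhibitors 3 of 18 were higher (4 adjusted over the list alone): Timp1, the macrophage elastase gene Mmp12 (1.05) and Timp2 (0.59). Of the 18 quiescence and retinoid genes 2 were higher (3 adjusted over the list alone), among them Cygb (1.00). Vim (0.41), Adm (0.60) and Fcgr2b (0.54) were the only members that passed in the myofibroblast, vascular and endothelial lists. Among immediate-early genes Junb (-0.51) and Dusp1 (-0.49) were lower (1 higher and 3 lower adjusted over the list alone), and among stress genes Calr (-0.47). Dusp1 no longer passed without the disturbed spots (-0.78, adjusted p = 0.0823). The arrays (1 animal and pool) read 0.70 and 1.43 for Col3a1 and 0.66 and 1.43 for Mmp12. With Feature Extraction log ratios Col3a1 stood at 0.63, Timp2 at 0.22, Vim at 0.21, Adm at 0.35 and Dusp1 at -0.93.

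As a list, the 32 interferon response genes were lower in untreated cells with a median of -0.15 (adjusted p = 5.7e-04, but adjusted p = 0.9463 with an estimated correlation); Bst2 was the member that passed (1 higher and 4 lower adjusted over the list alone). The 17 p53 targets had a median of -0.05 with Phlda3 lower (1 adjusted over the list alone; list adjusted p = 0.0181, but adjusted p = 0.9463 with an estimated correlation). The 25 inflammatory genes had a median of 0.06 (adjusted p = 0.0432, but adjusted p = 0.9463 with an estimated correlation) without a member that passed (3 higher adjusted over the list alone). Without the pooled untreated array the interferon list (median -0.02, adjusted p = 0.8604) and the p53 list (0.02, turned, adjusted p = 0.4485) did not pass, and the inflammatory median was 0.29. Without the 1-animal untreated array the inflammatory list did not pass (median 0, adjusted p = 0.6222), and the interferon and p53 medians were -0.30 and -0.11. With Feature Extraction log ratios none of these lists passed, with medians of -0.20 for interferon genes (adjusted p = 0.0867), -0.17 for p53 targets (0.0867) and 0.03 for inflammatory genes (0.1816). Without the disturbed spots the inflammatory list did not pass (0.03, adjusted p = 0.1263) and the p53 median was -0.10. With median centring the p53 call ended (-0.04, adjusted p = 0.3481) and the inflammatory median was 0.21. The other 17 lists did not pass, and in 4 of them median, mean and test differed in sign. These were the myofibroblast genes (0.09, -0.05, up), endothelial markers (median -0.00, mean 0.03, up), cholangiocyte markers (-0.01, 0.01, up) and portal markers (median 0, mean -0.07, down).

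By limma 181 genes differed between untreated and control siRNA cells, 111 higher and 70 lower, with 3476 at an unadjusted p under 0.05. Of the 181, 21 differed at least 2-fold (20 higher, 1 lower), and 11 genes were at least 2-fold on both arrays, all higher, where independent arrays would give 0.06. Without the disturbed spots 462 genes passed (274 higher, 188 lower), among them 175 of the 181, and 20 were 2-fold on both arrays. Without background correction the counts were 513 and 26, and without the filter on dim probes 357 genes passed. No gene passed in limma with Feature Extraction log ratios (3331 at an unadjusted p under 0.05), the deposited value table (3332), median centring (73) or scaling between arrays (580). All 181 genes kept their sign with Feature Extraction log ratios and with median centring. Without the pooled untreated array limma called 0 genes (1995 at an unadjusted p under 0.05), and without the 1-animal untreated array 34, with 14 of the 35 named genes among them. Without either endoglin siRNA array 760 genes passed. The 2-fold counts were 53 without the 1-animal untreated array, 39 without the pooled one, 62 with Feature Extraction log ratios, 60 with the deposited table and 0 with scaling.

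Both comparisons with control siRNA overlapped. Of the 111 genes that were higher in untreated cells, 62 were shared, against 5.83 for independent draws. Of the 70 that were lower, 66 were shared, against 2.01. Across genes, which are not independent replicates, the mean ratios of both groups had a correlation of 0.533 and a covariance of 0.0146. Values simulated with no effect and a fully shared control RNA gave a correlation of 0.493. The covariance calculated for this case from the prior variance was 0.0024. A second simulation run through the whole test gave a correlation of 0.506 and a covariance of 0.0039 with no gene called by limma. Neither simulation held a dye effect or a feature of the control RNA common to both RNA sources. Between the 1-animal array of one group and the pooled array of the other the covariance averaged 0.0123. Part of the overlap can come from the control RNA and from the dyes, which both comparisons share, so it is not a count of genes that both conditions changed.

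The comparison of endoglin siRNA with untreated cells removes any dye effect common to all arrays, but also holds any effect of transfection itself. Endoglin loss and transfection cannot be told apart in it. Higher in endoglin siRNA cells were Oit3 (1.19 ± 0.11, SE, n = 2 arrays; adjusted p = 0.0256), Tm4sf1 (1.19 ± 0.09), and the peptidylarginine deiminase genes Padi3 (1.16) and Padi4 (0.75). Ephx1 (microsomal epoxide hydrolase, 0.98), the protease inhibitor gene Slpi (0.93) and Rspo3 (an enhancer of Wnt signalling, 0.74) also rose. Lower were Spp1 (-1.67 ± 0.16, 3.18-fold, adjusted p = 0.0256), Rgs4 (a regulator of G-protein signalling, -1.59), Hsp90ab1 (-1.19), Ltbp2 (-1.19), the chemokine gene Cxcl12 (-1.04), the ectonucleotidase gene Enpp1 (-0.94) and the transcription factor gene Bhlhe41 (-0.72, with a second probe at -0.00). Macrophage genes were lower as well: Fcrl2 (-1.51), the complement gene C1qa (-1.09), Ctss (-1.04) and the MHC class II chaperone gene Cd74 (-0.95). Cd74 stood at -1.44 without the disturbed spots and -1.87 with Feature Extraction log ratios. With median centring Cxcl12 stood at 0.04 and Enpp1 at 0.03.

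Genes that did not pass were also named by rank of the smaller of their ratios in both RNA sources, not of the mean: A2m (-3.15, adjusted p = 0.068; 0.0175 without the disturbed spots), Akr1c15 (1.33, with 1.79 for 1 animal and 0.87 for the pool, adjusted p = 0.1101; 0.0024 without them), Gpc3 (1.18, adjusted p = 0.3953), Clu (2.14-fold higher, adjusted p = 0.0658; 0.0217 without them), Fmod (1.09, adjusted p = 0.2564) and Cxcl1 (0.88, adjusted p = 0.6931). Among genes named in the other comparisons, Lyz2 (-2.22, adjusted p = 0.127), Ccn4 (-1.86, adjusted p = 0.1766), Cthrc1 (-1.76, adjusted p = 0.1318) and Tgm2 (-1.34, adjusted p = 0.2791) also had large differences that did not pass. With Feature Extraction log ratios Akr1c15 (2.47), Gpc3 (1.82) and Cxcl1 (1.39) were more than 1.5 times as large. With the RNA source (1 animal or pool) as a block all of the ranked genes passed, with adjusted p-values from 2.1e-04 (A2m) to 0.0144 (Akr1c15). Of the genes chosen for naming in this comparison that had not passed, 22 did so with the block and 14 still did not. Lyz2, Ccn4, Cthrc1 and Tgm2, chosen in the other comparisons, were not among these.

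As lists, the 20 macrophage markers were lower in endoglin siRNA than in untreated cells, with 3 members lower (10 adjusted over the list alone) and a median of -0.61 (adjusted p = 2.4e-21, but adjusted p = 0.1821 with an estimated correlation). This median was -1.28 with Feature Extraction log ratios and -0.33 without the 1-animal untreated array. Beside this shift, collagens (median -0.28, adjusted p = 7.1e-11), TGF-beta targets (-0.27, 9.9e-09), matrix proteases (-0.16, 4.6e-05) and myofibroblast genes (-0.17, 2.9e-05) were lower, each with an adjusted p of 0.1821 with an estimated correlation. Median centring turned their medians to 0.68, 0.51, 0.40 and 0.78. Without the 1-animal endoglin array the medians of TGF-beta targets, proteases and myofibroblast genes were -0.17, -0.06 and -0.11, all still passing. Without the pooled endoglin array that of proteases was -0.29, and without the pooled untreated array that of myofibroblast genes was -0.08. Ltbp2 was the only member of these that passed, while 6 collagens, 7 TGF-beta targets, 3 proteases and 2 myofibroblast genes were lower adjusted over the list alone. Cholesterol synthesis genes (-0.18, adjusted p = 1.1e-08, but adjusted p = 0.4099 with an estimated correlation), co-receptors (-0.05, 0.0080, but adjusted p = 0.5814 with an estimated correlation) and portal markers (-0.13, 0.0328, but adjusted p = 0.5358 with an estimated correlation) were lower too, with medians of 0.49, 0.06 and 0.09 under median centring. The sterol median was -0.38 with Feature Extraction log ratios, -0.32 without the disturbed spots and -0.09 without the pooled untreated array. The co-receptor median was -0.16 and -0.08 in the first 2 of these settings and lay between -0.10 and 0.01 with 1 array left out, so it turned sign without the 1-animal endoglin array. The portal median was -0.01 and -0.06 in the same 2 settings, and the portal call ended without the filter on dim probes (-0.09, adjusted p = 0.075). Each of these lists had 1 member lower adjusted over the list alone. The co-receptor list did not pass without Eng, the target of the siRNA (median -0.04, adjusted p = 0.0678), an alternative chosen after seeing the data.

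Upward shifts against untreated cells, also beside the lower macrophage markers, were found for cell cycle genes (median 0.24, adjusted p = 1.4e-06) and p53 targets (0.24, 3.5e-05), each with an adjusted p of 0.4099 with an estimated correlation. Immediate-early genes (0.16, 0.0017; adjusted p = 0.5814 with an estimated correlation), BMP targets (0.18, 0.0020; adjusted p = 0.2606 with an estimated correlation) and interferon response genes (0.12, 0.0012; adjusted p = 0.6346 with an estimated correlation) shifted upward as well. No single member of these lists passed in limma; adjusted over the list alone 4 p53 targets, 3 BMP targets and 2 immediate-early genes did, and 0 cell cycle and interferon genes. The largest differences were Gdf15 (0.78) and Btg2 (0.69) among p53 targets, Dusp6 (0.77) among immediate-early genes, Id1 (0.76) among BMP targets, Bst2 (0.72) among interferon genes and Cdk1 (0.54) among cell cycle genes. With the RNA source as a block Gdf15, Btg2, Dusp6 and Bst2 passed (adjusted p = 0.0267, 0.0341, 0.024 and 0.0172), and Id1 (0.1014) and Cdk1 (0.0872) did not. In the list test against control siRNA, interferon genes (median 0.01), p53 targets (0.14) and immediate-early genes (0.05) did not pass. Cell cycle genes (0.20) and BMP targets (0.24) passed there. In untreated against control siRNA cells the interferon and p53 medians were -0.15 and -0.05. Without the pooled untreated array the interferon (median 0.03, adjusted p = 0.7136) and immediate-early lists (0.07, adjusted p = 0.0658) did not pass. Without the 1-animal endoglin array the interferon list (0.04, adjusted p = 0.2541), the co-receptors (0.01, adjusted p = 0.0759) and the portal markers (-0.05, adjusted p = 0.0903) did not, and the BMP target median was 0.33. The portal markers did not pass without the 1-animal untreated array either (-0.00, adjusted p = 0.2835), where the interferon median was 0.30; without the pooled endoglin array the interferon median was 0.20. With Feature Extraction log ratios the interferon (0.12, adjusted p = 0.4916), BMP target (0.27, adjusted p = 0.0782) and portal lists (-0.01, adjusted p = 0.0736) did not pass, and the immediate-early median was 0.25. Without the disturbed spots the interferon list did not pass (0.08, adjusted p = 0.147). With median centring the medians of the upward lists lay between 0.72 (cell cycle) and 1.00 (interferon). Median centring ended the calls of co-receptors (0.2589), proteases (0.7298), portal markers (0.3242), TGF-beta targets (0.5903) and cholesterol synthesis genes (0.1209).

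In all 13 of 21 lists passed in this comparison, 5 upward and 8 downward, and none with an estimated correlation, where the lowest adjusted p was 0.1821. That second test again rests on 2 residual degrees of freedom. Among the other lists, inflammatory genes had Cxcl12 lower (3 higher and 1 lower adjusted over the list alone; median 0.11), the endothelial list had Oit3 higher, and the cholangiocyte list had Spp1 lower. Median, mean and test differed in sign for quiescence genes (-0.01, 0.04, down), vascular genes (-0.01, 0.02, down), endothelial markers (-0.02, 0.02, down) and cholangiocyte markers (median 8.2e-05, mean -0.19, down).

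By limma 26 genes differed between endoglin siRNA and untreated cells, 11 higher and 15 lower, and 2100 had an unadjusted p under 0.05; 17 of the 26 differed at least 2-fold. With the RNA source (1 animal or pool) as a block 269 genes passed, and without the disturbed spots 198 (59 higher, 139 lower), all of the 26 being among them in both cases. Without background correction 168 passed, without the filter on dim probes 47, and with the mean of all probes 17. No gene passed in limma with Feature Extraction log ratios (2779 at an unadjusted p under 0.05), the deposited table (2775), median centring (260) or scaling between arrays (351). All 26 genes kept their sign with Feature Extraction log ratios, and median centring turned 3 of them. Without the pooled untreated array limma called 0 genes (1234 at an unadjusted p under 0.05) and without the 1-animal untreated array 1, whereas 52 passed without the 1-animal and 434 without the pooled endoglin siRNA array.

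In endoglin siRNA cells 21 genes differed from both control siRNA and untreated cells, 11 higher and 10 lower. A dye effect common to all arrays cancels in the second of these differences, but a difference in control RNA does so only if the arrays shared it, which the labels do not state. Those with a symbol were, with their ratios to control siRNA, Tm4sf1 (1.23), Oit3 (0.88), Rspo3 (0.80), Ephx1 (0.78), Padi3 (0.76), Slpi (0.56) and Padi4 (0.51) on the higher side. On the lower side stood Hsp90ab1 (-1.47), Rgs4 (-1.13), Ltbp2 (-1.05), Enpp1 (-0.87), Cxcl12 (-0.76) and Spp1 (-0.49); with median centring Rgs4 (0.24), Enpp1 (0.28), Cxcl12 (0.62) and Spp1 (0.52) had positive ratios to control siRNA. The count was 162 without the disturbed spots, 173 with the RNA source as a block, 139 without background correction, 37 without the filter on dim probes and 13 with the mean of all probes. It was 34 without the 1-animal and 410 without the pooled endoglin siRNA array, 1 without the 1-animal untreated array and 0 by limma without the pooled one. It was also 0 by limma with Feature Extraction log ratios, the deposited table, median centring and scaling.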

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

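The background fit without the 10 disturbed spots, leaving out arrays for the gene lists, and leaving endoglin out of its co-receptor list were chosen only after the result was seen; the other alternatives were chosen before the data were examined.

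Median centring in place of loess left no gene past the limma test in any comparison, and gave an endoglin ratio of -1.34 (adjusted p = 0.2118) and 2384 genes at least 2-fold on both arrays after endoglin siRNA, against 20. It turned these genes of endoglin siRNA against control siRNA: Mmp23 (0.92), Lox (0.69), Nes (0.66), Idi1 (0.65), Hmgcs1 (0.62), Cxcl12 (0.62), Spp1 (0.52), Calr (0.48), Phlda3 (0.48), Col1a1 (0.45), Junb (0.43), Bmp6 (0.33), Pmepa1 (0.32), Stat2 (0.32), Enpp1 (0.28), Vegfa (0.27), Rgs4 (0.24), Mfap5 (0.03) and Sphk1 (0). Against untreated cells it turned Cxcl12 (0.04) and Enpp1 (0.03). The direction of the list test turned against control siRNA, with these medians, for myofibroblast genes (1.03), interferon response (0.87), ligands and Smads (0.83), vascular signalling (0.82), collagens (0.70), TGF-beta targets (0.67) and cholesterol synthesis (0.62). The medians of interferon response (0.01), ligands and Smads (0.07) and vascular signalling (0.03) had been positive before. Against untreated cells the test turned for quiescence genes (0.79), myofibroblast genes (0.78), collagens (0.68), vascular signalling (0.68), TGF-beta targets (0.51) and cholesterol synthesis (0.49). The median became positive while the test kept its direction for co-receptors (0.13) against control siRNA, and for proteases (0.40), portal markers (0.09) and co-receptors (0.06) against untreated cells. For the comparison with control siRNA the construction shows the cause, as median centring leaves in how the log2 ratio changed with intensity before loess. On the endoglin siRNA arrays it rose from 0.08 and 0.07 in the dimmest to 1.69 and 1.58 in the brightest 10% of spots. Untreated array 1 had a similar rise, from 0.05 to 1.53, whereas untreated array 2 went the other way, from 2.56 to 1.82. That array takes part in the turns against untreated cells, and its share in them was not tested.

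Feature Extraction log ratios and the deposited value table left no gene past the limma test in any comparison, gave endoglin at -2.44 (adjusted p = 0.0747), and gave 302 and 300 genes 2-fold on both arrays after endoglin siRNA and 62 and 60 in untreated cells, against 20 and 11. The cause was not tested for these 2 settings. Scaling between arrays also left no gene, with endoglin at -3.56 (adjusted p = 0.4355) and 2-fold counts of 8 and 0. Scaling sets the spreads of the arrays equal by construction. Before it the median absolute deviation of gene spots was 0.167 on the 1-animal and 0.023 on the pooled endoglin siRNA array. Scaling thus stretched the pooled ratios relative to the 1-animal ones, and the SE for endoglin was 1.24 against 0.26. Without background correction the counts rose to 4505 (endoglin siRNA against control siRNA), 513 (untreated against control siRNA), 168 (endoglin siRNA against untreated) and 139 (against both), with 72 and 26 genes 2-fold; the cause was not tested.

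Without the disturbed spots the counts were 4158, 462, 198 and 162, with 57 and 20 genes 2-fold. The construction shows the cause, as these spots widened the fitted background and flattened the pooled ratios. Without a filter on dim probes 357 genes passed in untreated cells, 47 between endoglin siRNA and untreated cells and 37 against both. The mean of all probes gave 17 and 13 for the last 2 of these. Only the arrays of the group gave 1174 and 760 genes against control siRNA. The RNA source as a block gave 269 genes between endoglin siRNA and untreated cells and 173 against both. The cause was not tested for these settings.

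Leaving out 1 array moved the counts to between 898 and 2683 for endoglin siRNA against control siRNA, 0 and 760 for untreated against control siRNA, 0 and 434 for endoglin siRNA against untreated, and 0 and 410 against both, each 0 by limma. The 2-fold counts were 31 to 155 and 39 to 53, and endoglin ranged from -3.08 to -1.72. With 1 endoglin siRNA array the spread came from the untreated arrays alone, with an SE for endoglin of 0.09 against 0.26, so its passing there is no test of stability. The list of cholesterol synthesis in untreated cells, which did not pass with all arrays, passed at -0.10 without the pooled untreated array, against 0.03 with all arrays, and passed upward at 0.14 without the 1-animal untreated array. The cause was not tested.

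Of 1494 results of named genes that passed, under settings that kept all arrays, 908 were the same, 565 weaker and 21 turned; of 544 with 1 array left out, 382 were the same and 162 weaker. Of 127 list results that passed, 74 were the same, 45 weaker and 8 turned; with 1 array left out 89 of 100 were the same and 11 weaker. Of results that had not passed, 50 of 556 for named genes passed under settings that kept all arrays, and 33 of 204 with 1 array left out. For lists these were 23 of 191, with 5 more passing in the other direction, and 23 of 152, with 1 more in the other direction. A block for slide or scan was not run, because all arrays lay on 1 slide and in 1 scan. Signal over background limits the reading of dim genes, as 61.9% to 87.2% of gene spots were well above background in Cy3.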

Other observations

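The tests of a common dye effect and of fewer macrophages were chosen only after the result was seen; those of exchanged dyes and of a smaller stellate cell share were set before the data were examined. All 20 measured macrophage markers had positive ratios in untreated against control siRNA cells (median 0.88), with the brightest at mean log2 intensities of 12.5 (Lyz2, 1.70), 12.3 (Cd14, 0.50, also expressed by stellate cells) and 11.9 (Laptm5, 1.21), and none of them belonged to another list. An exchange of dyes is argued against by a median Cy3 difference of 0.05 (spread 0.17) where it required -0.44 or lower, and a common dye effect by a marker median of -0.61 between endoglin siRNA and untreated cells, where it cancels; the spread used there, 0.25 between both RNA sources, replaced the interquartile range over markers after a first output, and with that range the value would not lie beyond it. A smaller share of macrophages in transfected cultures stays open. For it, 95% of the markers were higher in untreated than in both kinds of transfected cells on all arrays. That share largely restates the pattern and reuses the same untreated ratios, so it cannot decide the question. Whether macrophages were fewer or expressed less also stays open. A smaller share of stellate cells in the untreated culture cannot be told apart from fewer macrophages in the transfected cultures. The largest median of the other marker lists was 0.02 (spread 0.06), which met the value set against a smaller stellate cell share. After a first output that verdict was withdrawn, because few of these markers were as bright as the median macrophage marker. They were 0 of 16 hepatocyte and only 4 endothelial and 2 cholangiocyte markers. Kdr (-0.03), Sox9 (0.03), Oit3 (-0.31) and Esam (-0.36) went against a smaller stellate cell share, and Fcgr2b (0.54) and Spp1 (1.18) with it.

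The test of this pattern was set before the data were examined. The 2075 genes that passed in endoglin siRNA against control siRNA cells could follow the siRNA, or could carry a dye effect or a feature of the control RNA. The change against untreated cells divided by that against control siRNA had a median of 0.57 (interquartile range 0.48), between the values set for either reading. It was 0.25 or lower for 18.5% of the genes, above 0.75 for 31.7% and below 0 for 6.5%. Endoglin siRNA and a dye or control RNA effect cannot be told apart for the whole group; arrays with the dyes exchanged would separate the dye effect, but not a feature of the control RNA.

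The tests of this pattern were chosen only after the result was seen, and that of the disturbed fit was written with its exploratory values known. Of 48 genes other than endoglin that passed and were at least 2-fold, 43 responded less on the pooled than on the 1-animal endoglin siRNA array, with a median quotient of 0.63. Compressed ratios on the pooled array cannot be told apart either: the quotient of spike-in slopes was 1.01 and that of the responses in Feature Extraction log ratios 0.76, a gap within the spread of 0.32 over genes; that comparison replaced the one with 0.63 after a first output. More endoglin mRNA left in the pooled cells might contribute, as the endoglin quotient was 0.56, but it cannot be told apart: the verdict was withdrawn after a first output because without the disturbed spots endoglin had 0.61 and the other genes 0.82. The disturbed background fit could likewise account for part. Leaving out its spots moved the quotient to 0.82, and 40 of the 48 genes stayed smaller on the pool. These 48 genes were picked by mean size in the disturbed fit, which favours genes with a large 1-animal ratio. Counts and quotients over them therefore cannot decide between the explanations. Over all genes, without this choice, the quotient of SDs moved from 0.67 to 1.02. The share of the fit in the pattern cannot be told apart from the other explanations.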
